A study of Mus musculus with 30 samples.

How the data were processed

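Gene expression was measured on Affymetrix Clariom HT mouse arrays in neutrophils, macrophages and microglia sorted from the ischemic hemisphere of TREM1 knockout and wild-type mice. Per the labels, RNA with an integrity number above 7.5 was used, and 0.6 to 0.8 ng of it was made into labelled cDNA. The intensities deposited by the authors were made with RMA, which corrects background, normalizes between arrays and summarises probes. Its version and the set of arrays normalized together are not stated. The table held linear intensities from 5.62 to 438297, with 22103 transcript clusters on 30 arrays, none missing and none a control. Their log2 was taken without a pseudocount, and no cluster was left out. Gene symbols came from the deposited platform annotation and were checked by gene number against the RefSeq annotation of GRCm38.p6. Of the clusters, 19508 had 1 symbol, for 19479 genes, and 2595 were not in the annotation.

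Arrays were grouped by genotype and cell type as labelled, giving 6 groups of 3 to 6 arrays. A linear model with 1 mean per group was fitted to all 30 arrays with limma 3.58.1 in R 4.3.3, with 24 residual degrees of freedom and moderated t tests. The comparisons drawn from it were KO against WT within each cell type, WT cell types against each other, and the difference between 2 cell types in the change with genotype. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, and every adjusted p of a gene in the text is from limma. Differences are log2 with the SE of the model, and levels are log2 intensities with the SD over arrays. Signal over background was not given per array, so the median intensity and the share of the brightest clusters describe each array.

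Gene lists, 39 of them, were fixed before the data were examined, and the 38 with at least 5 measured genes were tested. The lists held 714 genes, of which 644 were measured. Each list was tested against all other genes with camera of limma at a preset correlation between genes of 0.01. The test was repeated with the correlation estimated per list, and with fry, which does not compare a list with other genes. A list of 25 measured cartilage genes was written after the data had been seen.

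The genes to name were chosen by a rule fixed before the data were examined. It used clusters with exactly 1 symbol and the brightest cluster of a gene, and left predicted and clone-named models counted but unnamed. Trem1 came first in each comparison of genotypes. Then came the 8 most increased and the 8 most decreased genes that passed and whose brighter group mean was at or above the median of all cluster means, 6.69. Where fewer passed, all were named, and where none passed, the 4 with the smallest p were given as values. Up to 4 members of each described list with the smallest p followed. The WT comparisons named 8 genes in each direction and up to 4 members of each marker list, and differences between cell types in the change with genotype named 5 in each direction.

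Alternatives chosen before the data were examined were quantile normalization over all arrays or within cell types, median centring, array weights, a variance trend with a robust prior, leaving out the dimmest 25% of clusters, 1 cluster per gene, a fit on only the arrays compared, the replicate number as a block, and each array left out in turn. Settings with a covariate, with KO microglia 2 and 4 both left out, and with WT neutrophil 4 left out of a fit on the neutrophil arrays alone were added after the data were seen. Up to 100 other splits of the arrays were drawn with seed 1. In groups of 4 to 6 arrays, an array far from the others was found with the Dixon test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

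The fit was tested on simulated data with the group sizes of the study and 50 changed clusters at each of 4 sizes. For KO against WT neutrophils it recovered 60% of changes of 1 log2 unit and 98% of changes of 2. The shares were 54% and 92% in macrophages and 60% and 98% in microglia, while changes of 0.5 were recovered in 8%, 8% and 16%. Among all calls in these runs 4.35%, 6.62% and 6.8% were on unchanged clusters. The simulated noise was independent between clusters, with 1 spread per cluster in all groups. In the data the WT neutrophil arrays spread more, with a median SD of 0.38 against 0.28 to 0.3 in the other groups. The simulated rates may therefore not hold for the neutrophil comparison.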

Results

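The series measured gene expression in myeloid cells sorted from the ischemic hemisphere of mice with and without TREM1, a receptor on myeloid cells that amplifies inflammatory signalling through an adaptor carrying an immunoreceptor tyrosine-based activation motif. Per the labels, male C57BL/6 mice of 8 to 10 weeks, knockout (KO) or wild type (WT), underwent occlusion of the middle cerebral artery for 45 min, a model of ischemic stroke, and cells were taken 48 h after reperfusion. Neutrophils were sorted as CD45 high, CD11b positive and Ly6G positive cells, macrophages as CD45 high, CD11b positive and Ly6G negative cells, and microglia as CD45 low, CD11b positive cells, whose gate the labels also give as Ly6G positive. The 30 arrays fell into 6 groups, with 4 WT and 5 KO neutrophil arrays, 3 WT and 6 KO macrophage arrays, and 6 WT and 6 KO microglia arrays.

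Each array held 22103 transcript clusters, and the number of arrays limits the precision of every value below. The median intensity per array was 97.7 to 108 in WT neutrophils, 89.3 to 97.9 in KO neutrophils, 83.7 to 86 in WT macrophages, 85.1 to 91.1 in KO macrophages, 107 to 120 in WT microglia and 110 to 116 in KO microglia. The 100 brightest clusters held 26.1% to 27.6% of the summed intensity in WT neutrophils, 24.3% to 25.9% in KO neutrophils and 19.7% to 21.8% in the other groups. The first principal component held 50.5% of the variance and separated microglia from the other cells, and the second held 22.5% and separated neutrophils from macrophages. On the second component the WT neutrophil arrays lay from 59.5 to 116.1, the KO neutrophil arrays from 5.4 to 50 and the macrophage arrays from -79 to -64.6. Within a group, the mean correlation of an array with the others was 0.974 to 0.988, except in WT neutrophils, where it was 0.933 to 0.962.

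**Figure D1:**
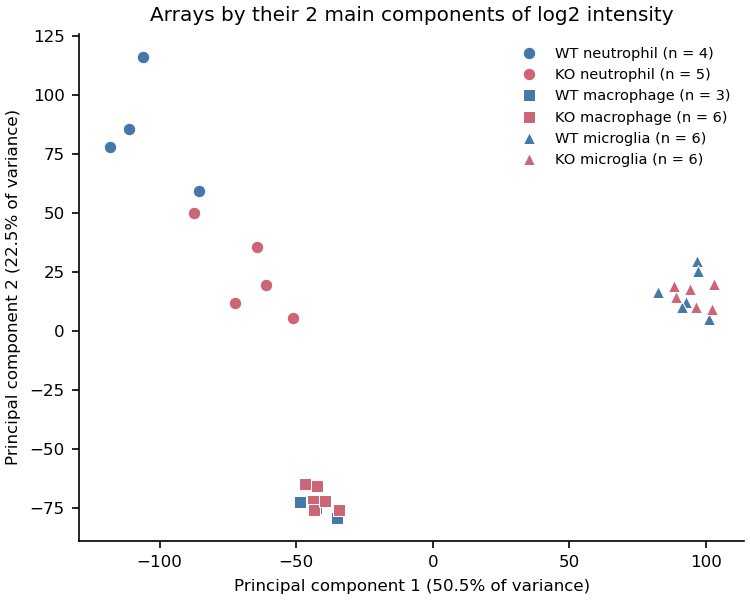
Each point is 1 array, placed by its scores on the first (x axis, 50.5% of the variance) and second (y axis, 22.5%) principal components of log2 intensity, with color for genotype and shape for cell type. The KO neutrophil arrays, from 5.4 to 50 on the second component, lie between the WT neutrophil arrays (59.5 to 116.1) and the macrophage arrays (-79 to -64.6).

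Trem1 itself was brightest in neutrophils, at a log2 intensity of 17.20 ± 0.29 (SD, n = 4) in WT, against 13.96 ± 0.32 (n = 3) in WT macrophages and 9.60 ± 1.02 (n = 6) in WT microglia. The gene is on chromosome 17 in the GRCm38.p6 annotation, beside the related receptor genes Trem2 and Trem3. In KO cells its level was 15.98 ± 0.51 (n = 5) in neutrophils, 13.47 ± 0.53 (n = 6) in macrophages and 8.35 ± 0.68 (n = 6) in microglia. Trem1 fell by 1.22 on the log2 scale in KO neutrophils (SE 0.41, adjusted p = 0.0361), and all 5 KO arrays lay below the WT mean. The difference was -0.49 (SE 0.44, adjusted p = 0.998) in macrophages and -1.25 (SE 0.36, adjusted p = 1) in microglia, where all 6 KO arrays lay below the WT mean. The change in neutrophils differed from that in microglia by 0.02 (adjusted p = 0.985) and from that in macrophages by -0.73 (adjusted p = 0.455). The array summarises the gene in 1 value, the labels do not say which part of the gene was deleted, and a probe outside the deleted part checks nothing, so these levels do not test the genotype. The neutrophil call ended without KO neutrophil 1 (-1.01, adjusted p = 0.112), KO neutrophil 3 (-1.27, 0.0501), WT neutrophil 2 (-1.12, 0.0806) or WT neutrophil 3 (-1.20, 0.0729). Among the scaling and covariate settings it ended with quantile normalization over all arrays (-1.04, 0.0759), each array centred on its median (-1.11, 0.071) or the level of broadly expressed genes as a covariate (-1.96, 0.132). It passed with quantile normalization within cell types (-1.21, 0.042), with the level of broadly expressed genes that had not passed (-1.63, 0.0153) and with the cartilage mean (-1.74, 0.0223) as a covariate.

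**Figure D2:**
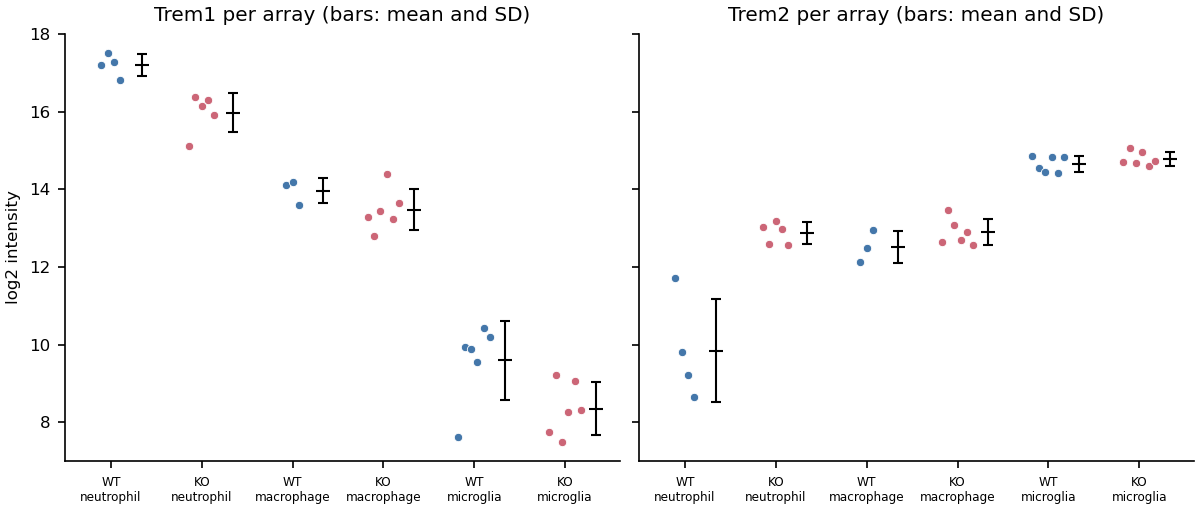
Log2 intensity (y axis) of Trem1 and of its neighbour Trem2 in each array of the 6 groups (x axis); points are arrays and bars are the mean and SD. Trem1 was 17.20 in WT and 15.98 in KO neutrophils on average, and Trem2 was 9.84 in WT and 12.87 in KO neutrophils.

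The comparison of KO with WT neutrophils asks what loss of TREM1 changes in the cells that expressed Trem1 at the highest level. Mertk, a receptor for the uptake of apoptotic cells, rose in KO neutrophils by 3.13 (SE 0.36, adjusted p = 2.34e-06), from 9.46 ± 1.09 (SD, n = 4) to 12.59 ± 0.60 (n = 5). Trem2, a lipid-sensing receptor of macrophages and microglia, rose by 3.03 (SE 0.34, adjusted p = 1.95e-06). Apoe, the main lipid carrier of the brain, rose by 2.46 (SE 0.40, adjusted p = 8.19e-05). Mmp8, the neutrophil collagenase, fell by 2.10 (SE 0.48, adjusted p = 0.00285), and Stfa1, a stefin of mouse neutrophils, fell by 1.91 (SE 0.31, adjusted p = 7.7e-05). For each of these 5 genes all 5 KO arrays lay on one side of the WT mean. With the level of broadly expressed genes per array as a covariate, a setting chosen after the data were seen, Mertk passed (2.05, adjusted p = 0.0463), while Trem2 (1.64, 0.0513), Apoe (0.76, 0.583), Mmp8 (-1.52, 0.421) and Stfa1 (-1.61, 0.1) did not. With the level of only those broadly expressed genes that had not passed, a covariate chosen by the calls themselves, all 5 passed (adjusted p of 0.0172 or less). In all, 2370 transcript clusters were higher and 2020 lower in KO, 4390 of 22103, and 7635 had an unadjusted p under 0.05. Changes of 2-fold or more were 1526 higher and 507 lower.

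The 8 genes with the highest positive change were Rab3il1, an exchange factor for Rab GTPases (3.64, SE 0.39, adjusted p = 1.25e-06), the carbonyl reductase Cbr2 (3.39, SE 0.71), the kinesin subunit Kif3a (3.36, SE 0.50), Cln8 of the endoplasmic reticulum (3.35, SE 0.77), the RNA helicase Ddx18 (3.31, SE 0.63), Lipo3 (3.24, SE 0.41), Tmem229b (3.23, SE 0.40) and the sugar phosphate exchanger Slc37a2 (3.14, SE 0.58). Their adjusted p lay between 1.25e-06 and 0.00285, and each was above the WT mean in 5 of 5 KO arrays. Ddx18 was 9.02 ± 2.71 in WT (SD, n = 4) and 12.33 ± 0.31 in KO (n = 5), and Cln8 was 7.96 ± 2.77 and 11.30 ± 1.34, so the WT arrays spread more. With the covariate for broadly expressed genes Ddx18 was at 0.34 (adjusted p = 0.929) and Cln8 at -0.54 (adjusted p = 0.886), so both calls ended and Cln8 changed sign. With the covariate from genes that had not passed they were at 2.09 (adjusted p = 0.00383) and 1.95 (adjusted p = 0.0404). Tmem229b in WT (4.91) and Mia (6.06) and Lipg (6.36) in KO lay below 6.69, the median of all cluster means, and were not shown to be above background, so the sizes and ranks of their changes are approximate. Among the 8 largest decreases were Cped1 (-2.85, SE 0.42), Ifitm6 of the interferon-induced transmembrane family (-2.83, SE 0.54), the lipase Lipg (-2.80, SE 0.44) and the metalloprotease Adam19 (-2.69, SE 0.31), with adjusted p from 2.34e-06 to 0.000561. The other 4 were genes of cartilage and connective tissue: Mia (-2.97, SE 0.94, adjusted p = 0.0262), the proteoglycan genes Dcn (-2.95, SE 0.97, 0.0314) and Lum (-2.74, SE 0.96, 0.0436), and Wif1, a secreted Wnt inhibitor (-2.82, SE 0.83, 0.0171). In WT neutrophil 4 the mean of a list of 25 cartilage genes, written after the values were seen, was 9.59, against 6.99 to 7.56 in the other WT neutrophil arrays and 6.28 to 7.32 in KO. Without that array the changes were -1.24 for Mia (adjusted p = 0.202), -1.87 for Dcn (0.197), -1.48 for Lum (0.283) and -1.48 for Wif1 (0.136), and at least 1 of these 4 calls also ended without KO neutrophil 1, 2, 3 or 4 or WT neutrophil 3 (adjusted p 0.0515 to 0.104).

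Of the 38 gene lists tested, 5 were higher and 1 lower in KO neutrophils. Of 27 measured genes of oxidative phosphorylation 19 rose, none fell and 8 did not pass, with 23 higher adjusted over the list alone. They included the complex I subunits Ndufa5 (1.37) and Ndufb5 (1.88) and the cytochrome c oxidase subunit Cox6c (0.75). The list median was 0.79 (adjusted p = 8.96e-13, and adjusted p = 0.313 with an estimated correlation). With the covariate for broadly expressed genes the call of this list ended and its direction reversed (adjusted p = 0.806), and the calls ended for repair and alternative activation (0.0949), disease-associated microglia (0.739) and border-associated macrophages (0.553). Phagocytosis and lipid handling (0.0241) and neutrophil markers (0.000767) passed with it. With the covariate from genes that had not passed all 6 lists passed, with oxidative phosphorylation at 3.15e-09, repair at 6.12e-05, disease-associated microglia at 0.0023 and border-associated macrophages at 0.0296. Of 18 genes of phagocytosis and lipid handling 13 rose and 1 fell, the same numbers adjusted over the list alone. Among the higher were Mertk, the lysosomal membrane gene Lamp1 (1.23) and the scavenger receptor Msr1 (1.56). Their median change was 1.45 (adjusted p = 1.93e-10, and adjusted p = 0.07 with an estimated correlation). Of 20 genes of repair and alternative activation 10 rose and none fell, 11 and 2 adjusted over the list alone, including the scavenger receptor Stab1 (1.59). The median over the list was 1.25 (adjusted p = 1.39e-05, and adjusted p = 0.07 with an estimated correlation). Of 16 genes described in disease-associated microglia 6 rose and none fell, the same adjusted over the list alone, including Gpnmb (2.39) and the protease Ctsb (0.73). These genes had a median of 0.93 (adjusted p = 0.000354, and adjusted p = 0.331 with an estimated correlation). Of 12 markers of border-associated macrophages 6 rose and 1 fell, the same adjusted over the list alone, including Siglec1 (1.97, from a WT level of 6.16) and Ms4a7 (2.08). Their median was 1.10 (adjusted p = 0.00692, and adjusted p = 0.331 with an estimated correlation). Of 20 neutrophil markers 6 fell and none rose, 11 lower adjusted over the list alone, and all 20 had a negative change. Stfa1, Cstdc4 (-2.01) and Mrgpra2b (-1.55) were among the lower. WT neutrophil 2 had a marker mean of 15.76, against 13.62 to 14.50 in the other WT arrays, and without it the difference in the marker mean went from -1.12 to -0.67 and the adjusted p of the list to 0.0483. The marker median was -0.96 (adjusted p = 0.000399, and adjusted p = 0.51 with an estimated correlation).

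**Figure D3:**
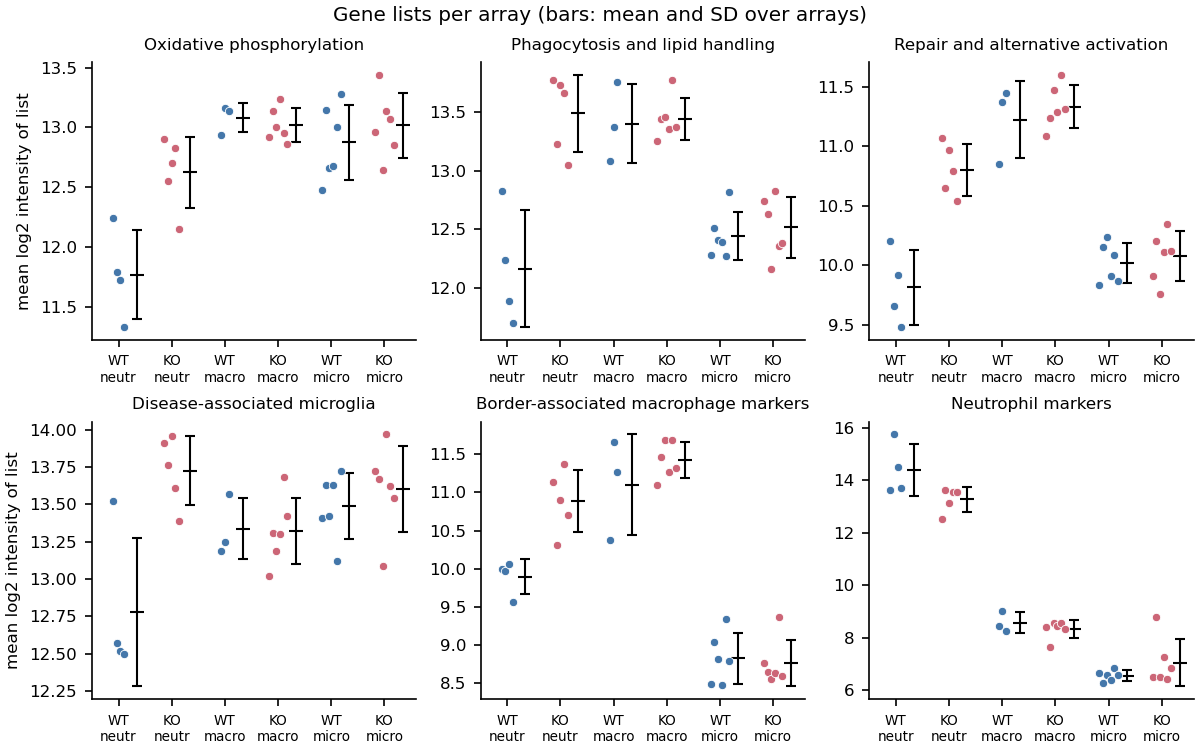
Mean log2 intensity (y axis) of the genes of 6 lists in each array, by genotype and cell type (x axis, neutr for neutrophils, macro for macrophages, micro for microglia); points are arrays and bars are the mean and SD. Neutrophil markers averaged 14.40 in WT (13.95 without WT neutrophil 2) and 13.28 in KO neutrophils.

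The lists that concern TREM1 signalling and inflammation did not pass by camera in KO neutrophils, although single members did. Of 17 genes of TREM1 and ITAM signalling 2 rose, including Lat2, an adaptor of myeloid receptors (1.75, adjusted p = 8.19e-05), and 4 fell, including Bcl10, a scaffold on the route to NF-kB (-0.85, adjusted p = 0.00258). In this list 2 were higher and 5 lower adjusted over the list alone. Of 19 inflammatory cytokines 3 fell and none rose, the same adjusted over the list alone, including Ltb (-1.48, adjusted p = 0.00179) and Tnfsf14 (-0.99, adjusted p = 0.00706). The cytokine list was lower by fry (adjusted p = 0.00698, against 0.118 by camera), with 3 of 19 positive, a median of -0.32 and a mean of -0.50. Lists of other cell types were lower by fry with similar medians, such as astrocyte (-0.31, adjusted p = 0.0148), neuronal (-0.31, 0.0364) and mast cell markers (-0.33, 0.00439), and the median of all clusters was -0.13. Of 22 chemokines Cxcl16 rose (2.09, adjusted p = 1.19e-05) and 2 fell, including Cxcl3 (-1.34, adjusted p = 0.00635), the same adjusted over the list alone. Of 23 NF-kB targets only Bcl3 fell (-1.23, adjusted p = 0.0117), also adjusted over the list alone, and its call ended without WT neutrophil 4 (adjusted p = 0.0621). Of 20 genes of the Toll-like receptor pathway 5 rose and 2 fell, the same adjusted over the list alone, with the co-receptor Cd14 lower (-1.23, adjusted p = 0.00267) and the RNA receptor Tlr3 higher (1.88, adjusted p = 0.00276). Of 26 neighbours of Trem1 on its chromosome 3 rose, Trem2 among them, and 3 fell, including Ccnd3 (-1.30, adjusted p = 0.0035), the same adjusted over the list alone. With the covariate for broadly expressed genes none of the genes named in this paragraph passed (adjusted p 0.0513 to 0.71), although each kept its sign, with Lat2 at 0.38, Cxcl16 at 1.57 and Ltb at -1.57. With the covariate from genes that had not passed, all but Bcl3 (-1.16, adjusted p = 0.0524) passed.

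Effector and marker genes moved in both directions. Of 17 genes of the oxidative burst and reactive oxygen handling 5 rose, including catalase Cat (1.97, adjusted p = 0.000142) and Txnrd1 (2.04, adjusted p = 0.000336), and 3 fell, including the inducible nitric oxide synthase Nos2 (-2.00, adjusted p = 0.000426). Here 7 were higher and 3 lower adjusted over the list alone. Of 13 genes of MHC class II presentation 3 rose, including H2-DMa (2.13, adjusted p = 0.000121) and H2-DMb1 (2.41, adjusted p = 0.000153), and none fell, the same adjusted over the list alone. Of 12 complement genes 5 rose, including C3ar1 (1.88, adjusted p = 1.95e-06) and C1qb (2.70, adjusted p = 0.000258), and 3 fell, the same adjusted over the list alone. Of 20 genes of matrix remodelling 5 rose, including Mmp14 (2.13, adjusted p = 7.3e-05), and 4 fell, including Mmp8 and Mmp19 (-2.18, adjusted p = 0.00166), with 6 and 5 adjusted over the list alone. Median and mean of the matrix list were -0.02, while the set test pointed up (adjusted p = 0.467). Of 19 markers of monocytes and macrophages 6 rose, including Lyz2 (1.43, adjusted p = 6.53e-05), and 1 fell, with 7 and 3 adjusted over the list alone, and the list did not pass (median 0.18, adjusted p = 0.232). Of 19 markers of homeostatic microglia 3 rose, including Aif1 (2.63, adjusted p = 1.71e-05), and 3 fell, with 4 and 4 adjusted over the list alone. Of 13 genes of immature neutrophil granules 4 fell and none rose, with 5 lower adjusted over the list alone. By camera none of these lists passed, while by fry the oxidative burst (adjusted p = 0.0381) and complement (0.02) lists were higher and the immature granule list was lower (0.00962). The immature granule mean was 10.38 in WT neutrophil 2, and without it the difference went from -0.70 to -0.21, while without WT neutrophil 4 the oxidative burst difference went from 0.29 to 0.14. Of the genes named in this paragraph, with the covariate for broadly expressed genes C3ar1 passed (1.69, adjusted p = 0.013) and the others did not (adjusted p 0.195 to 0.793), although each kept its sign, with Cat at 0.62, H2-DMb1 at 0.87 and Nos2 at -0.98. With the covariate from genes that had not passed, all of them passed (adjusted p of 0.0172 or less).

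Beside these gene groups, the WT and KO neutrophil arrays differed in how they read genes that all macrophage and microglia arrays detected. Of 2015 transcript clusters at or above a log2 intensity of 11 in every macrophage and microglia array, with WT macrophage and WT microglia means less than 1 log2 unit apart, 20, 87, 103 and 201 lay more than 3 log2 units below the mean of those arrays in WT neutrophils 1 to 4, against 5 to 24 in the KO neutrophil arrays. Neutrophil arrays had no part in the choice of these clusters, so a low value can also be lower expression in neutrophils. The count of 4390 was 2883 without KO neutrophil 1, 2884 without WT neutrophil 4, and 1084 with only the neutrophil arrays in the fit, of which 1064 were among the 4390 with the same direction. With the median level of the 2015 clusters per array as a covariate, a setting chosen after the data were seen, 212 genes passed, 123 of them among the 4390 with the same direction. With the level of the 1154 of these clusters that had not passed, 1980 passed, 1819 of them among the 4390. Centring each array on its median moved the median of all clusters by 0.12 and the share of higher calls from 54% to 71.6%.

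**Figure D4:**
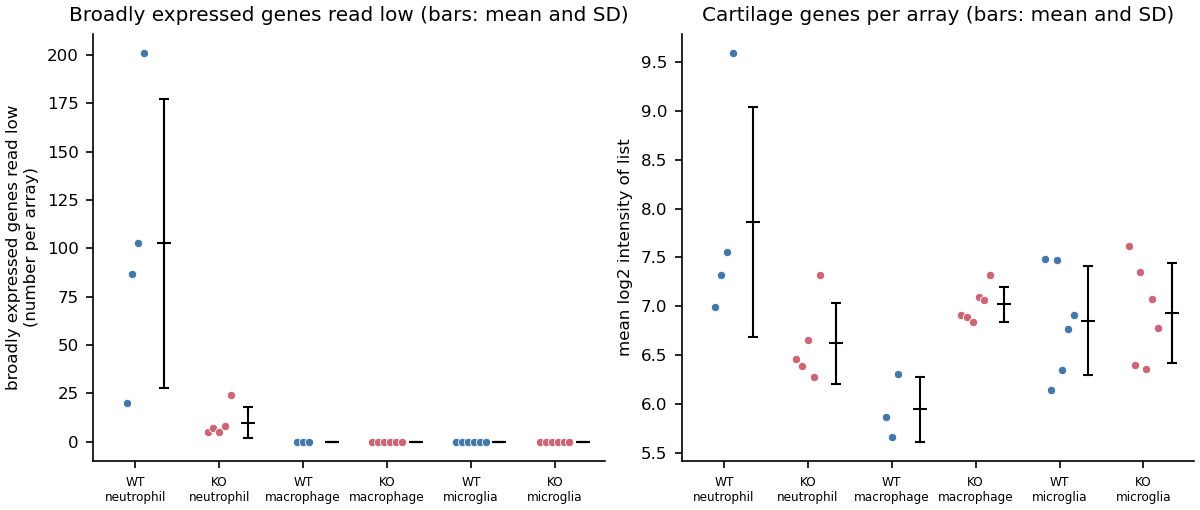
Left, the number (y axis) of 2015 broadly expressed transcript clusters that lay more than 3 log2 units below the mean of the macrophage and microglia arrays; right, the mean log2 intensity (y axis) of 25 cartilage genes; each by array and group (x axis), with bars for the mean and SD. WT neutrophil 4 had 201 low clusters and a cartilage mean of 9.59. The macrophage and microglia arrays had 0 low clusters, which follows from choosing clusters that were bright in all of them.

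In macrophages, where KO and WT cells were compared to ask the same question in recruited mononuclear cells, the only gene that passed was Grap2, an adaptor of antigen receptor signalling. Grap2 fell by 1.35 (SE 0.21, adjusted p = 0.0107), from 7.70 ± 0.13 (SD, n = 3) in WT to 6.35 ± 0.25 (n = 6) in KO, in 6 of 6 KO arrays. The KO level lies below 6.69 and was not shown to be above background, so the size is approximate. No gene passed in the other direction by limma, and 1029 had an unadjusted p under 0.05. Of the 4 genes with the smallest p on the higher side, Prg4, the lubricant of joints, differed by 5.31 (SE 1.12, adjusted p = 0.309) and Cytl1 by 5.71 (SE 1.26, 0.344). Dcn differed by 4.55 (SE 1.02, 0.376) and Sparc by 3.83 (SE 0.88, 0.376), and each of the 4 was above the WT mean in 6 of 6 KO arrays. Prg4, Cytl1 and Dcn belong to cartilage and connective tissue, while the matrix gene Sparc was also far higher in WT microglia than in WT macrophages. The mean of the cartilage list was 5.66 to 6.31 in WT and 6.84 to 7.32 in KO macrophages. Of 23 NF-kB targets none passed, also adjusted over the list alone, 4 had a positive difference, and the list was lower in KO with a median of -0.17 (adjusted p = 0.0182, and adjusted p = 0.872 with an estimated correlation). Its members with the smallest p were Traf1 (-0.90), Nfkbiz (-1.05), Nfkbie (-0.65) and Tnfaip3 (-1.14). No other list passed. The Grap2 call ended without WT macrophage 1 (-1.28, adjusted p = 0.211) or WT macrophage 2 (-1.37, 0.0684), while 9 genes passed without WT macrophage 3, with Cytl1 at 7.30 (0.0381), Prg4 at 6.55 (0.0388) and Sparc at 5.01 (0.0381). The NF-kB call ended without KO macrophage 1, 2 or 6 or WT macrophage 1 or 3 (adjusted p 0.0654 to 0.179).

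In microglia no gene passed between KO and WT by limma, with 646 at an unadjusted p under 0.05 and a smallest adjusted p of 0.284. Ifitm3, an interferon-induced antiviral membrane protein, differed by 0.69 (SE 0.16, adjusted p = 1), from 12.40 ± 0.26 to 13.09 ± 0.30 (SD, n = 6 each), and Esco2, which acts on sister chromatid cohesion, differed by 1.02 (SE 0.26, adjusted p = 1), each in 6 of 6 KO arrays. Entpd6 differed by 0.72 and Alg12 by 0.62, and on the lower side Cep295nl by -0.73, Usp36 by -0.60 and Engase by -0.95, all with an adjusted p of 1. Of the gene lists, 7 passed, 6 higher and 1 lower, while none of their members passed, and none passed adjusted over the list alone. Of 24 cell cycle genes 22 had a positive difference, among them Ube2c (1.16) and Ccnb2 (0.91), with a list median of 0.34 (adjusted p = 1.77e-06, and adjusted p = 0.642 with an estimated correlation). The mean of this list was 11.06 ± 0.64 in WT (10.13 to 11.79) and 11.45 ± 0.17 in KO (11.19 to 11.63), so all KO arrays lay within the wide WT range. Of 26 interferon response genes 19 were positive, among them Ddx58 (0.65), with a median of 0.32 (adjusted p = 0.00349, and adjusted p = 0.698 with an estimated correlation). Oxidative phosphorylation was higher with 25 of 27 positive and a median of 0.14 (adjusted p = 0.00429, and adjusted p = 0.824 with an estimated correlation). Its call ended without KO microglia 2 (0.501), WT microglia 1 (0.44) or WT microglia 4 (0.0792). Immediate early genes, which respond within minutes to stimuli such as cell dissociation, were lower with 5 of 22 positive, a median of -0.23 and the members Klf2 (-0.55) and Jun (-0.55) (adjusted p = 0.00429, and adjusted p = 0.698 with an estimated correlation). Without WT microglia 1 the adjusted p of this list was 0.416.

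The other 3 lists higher in KO microglia were markers of other cells. Of 20 neutrophil markers 17 were positive with a median of 0.30 (adjusted p = 0.00803, and adjusted p = 0.698 with an estimated correlation). Of 13 genes of immature neutrophil granules 10 were positive with a median of 0.22 (adjusted p = 0.013, and adjusted p = 0.642 with an estimated correlation). Ngp, a granule protein of maturing neutrophils, was at a log2 intensity of 13.11 in KO microglia 2 and 10.42 in KO microglia 4, against 5.53 to 7.60 in WT microglia, and the antimicrobial peptide gene Camp was at 12.46 and 8.04, against 4.63 to 5.29. Of 14 endothelial markers 8 were positive with a median of 0.10 (adjusted p = 0.0325, and adjusted p = 0.61 with an estimated correlation). Without KO microglia 2 the adjusted p was 0.73 for neutrophil markers, 0.501 for immature granule genes and 0.276 for endothelial markers. Without WT microglia 4 it was 0.0798 for immature granule genes and 0.0792 for endothelial markers, and the endothelial call also ended without WT microglia 2 (0.187) or WT microglia 3 (0.0764). The number of lists was 3 without KO microglia 2, 4 without WT microglia 4 and 1 without both KO microglia 2 and 4, a setting chosen after the data were seen. Without WT microglia 5, 1 gene passed.

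In WT mice the cell types were compared to ask how the sorted populations differ, and the gene of the Ly6G gate, Ly6g, was not analysed here. Against microglia, neutrophils were higher in the calprotectin gene S100a8 by 11.85 (SE 0.92, adjusted p = 9.21e-12), at 18.02 ± 0.29 (SD, n = 4) against 6.17 ± 0.85 (n = 6), and in Retnlg (11.50), Mmp8 (10.56), the decoy receptor gene Il1r2 (10.53), the gelatinase gene Mmp9 (10.41), Chil3 (10.39), Slfn4 (10.35) and Il1f9 (10.30). They were lower in the fructose transporter gene Slc2a5 (-7.43), Adamts1 (-7.00), Siglech (-6.52), Cd72 (-6.47), the mitotic kinase gene Cdk1 (-6.38), F11r (-6.22), Slamf9 (-6.21) and Pros1 (-6.17). Each of these 16 lay on one side of the microglia mean in 4 of 4 WT neutrophil arrays, with adjusted p of 3.97e-09 or less. Of 20 neutrophil markers 19 were higher, also adjusted over the list alone (median 8.72, adjusted p = 3.34e-21, and adjusted p = 0.0121 with an estimated correlation). Of 19 markers of homeostatic microglia 17 were lower and 2 higher, the same adjusted over the list alone (median -4.16, adjusted p = 2.33e-08, and adjusted p = 0.124 with an estimated correlation). In all, 4873 transcript clusters were higher and 7134 lower, 40.6% higher, a share that was 51.6% with each array centred on its median, which moved the median of all clusters by 0.14. In all WT comparisons, levels below 6.69, the median of all cluster means, such as 6.17 for S100a8 in microglia and 5.85 for Retnlg in macrophages, were not shown to be above background, so the sizes and the order of such differences are approximate. Neutrophil markers averaged 6.57 ± 0.21 (SD, n = 6) in WT microglia, whose gate the labels give as Ly6G positive.

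Against microglia, WT macrophages were higher in Plac8 (10.54), Chil3 (10.48), the MHC class II genes H2-Eb1 (10.39) and H2-Ab1 (9.33), the monocyte chemokine receptor gene Ccr2 (9.97), Plbd1 (9.74), Atp8b4 (9.66) and the monocyte antigen gene Ly6c2 (9.32). Ccr2 was at 15.32 ± 0.55 (SD, n = 3) in macrophages and 5.35 ± 0.18 (n = 6) in microglia (SE of the difference 0.64, adjusted p = 2.66e-13). They were lower in the matrix protein gene Sparc (-9.02), Nav3 (-8.03), Adamts1 (-7.81), the myelin protein gene Pmp22 (-7.53), Sgce (-7.53), Siglech (-7.22), Slc2a5 (-7.19) and the adhesion receptor gene Adgrg1 (-7.05). All 3 WT macrophage arrays lay on one side of the microglia mean for each of the 16, with adjusted p of 1.94e-09 or less. Of 19 markers of monocytes and macrophages 17 were higher, 18 adjusted over the list alone (median 5.08, adjusted p = 6.09e-32, and adjusted p = 3.38e-05 with an estimated correlation). Of 19 markers of homeostatic microglia 18 were lower (median -4.08, adjusted p = 3.4e-15, and adjusted p = 0.0171 with an estimated correlation). Of 14 dendritic cell markers 8 were higher, including Cd209a (6.59), and 4 lower (adjusted p = 0.000681, and adjusted p = 0.0368 with an estimated correlation). In all, 2126 were higher and 6159 lower, 25.7% higher, a share that was 49.7% after quantile normalization over all arrays and 66.5% with each array centred on its median, which moved the median of all clusters by 0.25 and 0.40.

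Neutrophils and macrophages of WT mice, both CD45 high, differed in neutrophil genes and in antigen presentation. Neutrophils were higher in Retnlg (10.58), the receptor gene Mrgpra2b (9.77), Il1f9 (9.23), the calprotectin gene S100a9 (9.13), Stfa2l1 (8.36), the chemokine receptor gene Cxcr2 (7.97), Sycp2 (7.91) and the sialyltransferase gene St3gal6 (7.89). Cxcr2 was at 16.43 ± 0.27 (SD, n = 4) in neutrophils and 8.46 ± 1.08 (n = 3) in macrophages (SE 0.35, adjusted p = 3.58e-16). They were lower in H2-Eb1 (-8.33), H2-Ab1 (-8.12), Ccr2 (-6.74), Klrb1b (-6.73), the potassium channel gene Kcnn4 (-6.62), H2-DMb1 (-6.61), Cd209a (-6.45) and Tifab (-6.42). Each of the 16 lay on one side of the macrophage mean in 4 of 4 neutrophil arrays, with adjusted p of 7.9e-09 or less. Of 20 neutrophil markers 19 were higher, also adjusted over the list alone (median 6.10, adjusted p = 1.41e-14, and adjusted p = 0.0537 with an estimated correlation). Of 19 markers of monocytes and macrophages 14 were lower and 1 higher, the same adjusted over the list alone (median -1.94, adjusted p = 1.09e-07, and adjusted p = 0.0626 with an estimated correlation). In all, 6550 were higher and 4852 lower, 57.4% higher, a share that was 38.7% with each array centred on its median, which moved the median of all clusters by -0.26. With only these 7 arrays in the fit 7299 passed.

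The change with genotype was then compared between cell types. Between neutrophils and microglia it differed for 1280 transcript clusters, 897 with a more positive change in neutrophils, with 5092 at an unadjusted p under 0.05. Rab3il1 differed by 3.67 (SE 0.51, adjusted p = 0.000157), Mertk by 3.41 (SE 0.48, adjusted p = 0.000157) and Ifitm6 by -3.33 (SE 0.72, adjusted p = 0.00563). Between neutrophils and macrophages it differed for 1518, 963 with a more positive change in neutrophils, including Mmp12, the macrophage elastase (4.27, SE 1.28, adjusted p = 0.041), and the exchanger gene Slc37a2 (3.37, SE 0.84, adjusted p = 0.0158). Cytl1 (-8.50, SE 1.74, adjusted p = 0.00526) and Prg4 (-8.03, SE 1.55, adjusted p = 0.00365) lay on the other side, and 5564 had an unadjusted p under 0.05. Between macrophages and microglia no gene passed by limma, with 761 at an unadjusted p under 0.05 and a smallest adjusted p of 0.555; Grap2 differed by -1.32 (SE 0.27). With only the arrays compared in the fit the counts against microglia and macrophages were 821 and 631, with the cartilage mean as a covariate 389 and 6, and with the level of broadly expressed genes as a covariate 45 and 9. The Mmp12 call ended in 12 of 18 fits that left out 1 array (adjusted p 0.054 to 0.104). Leaving out WT neutrophil 1 raised the counts against microglia and macrophages to 2611 and 2790 and leaving out KO neutrophil 5 to 2118 and 2418. Leaving out KO neutrophil 1 gave 724 and 827, and against macrophages the count was 919 without KO neutrophil 4 and 786 without WT macrophage 3.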

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

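The tests of explanations and the splits of arrays in this part were chosen after the results were seen, while the tests for differences between cell types and for arrays far from their group were chosen before the data were examined. The values screened for such arrays were partly chosen by the results, since they included the named genes, the lists that passed and the cartilage mean.

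The change with genotype differed between neutrophils and microglia for 1280 transcript clusters and between neutrophils and macrophages for 1518, each by a test of the difference itself. Against microglia the genes with the most positive difference were Rab3il1 (3.67), Cln8 (3.65), Cbr2 (3.51), Mertk (3.41) and Ddx18 (3.31), and those with the most negative were Ifitm6 (-3.33), Retnlg, a resistin-like gene of neutrophils (-3.02), Cped1 (-3.01), Lipg (-2.95) and Chil3, a chitinase-like protein gene (-2.84). Against macrophages they were Mmp12 (4.27), Ddx18 (3.71), Metap1d (3.49), Tmem229b (3.4) and Slc37a2 (3.37), and Cytl1 (-8.50), Prg4 (-8.03), Dcn (-7.50), Lum (-6.23) and Mxra8 (-5.91). Single arrays carried some of these calls. The Cbr2 call ended without KO neutrophil 1 (adjusted p = 0.052), KO neutrophil 4 (0.055) or WT neutrophil 3 (0.0524), and the Cln8 call without KO microglia 6, KO neutrophil 1, 3 or 4 or WT neutrophil 3 or 4 (0.0513 to 0.0805). The Retnlg call ended in 12 fits that left out 1 array (adjusted p 0.0545 to 0.111).

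For the KO and WT neutrophil count of 4390, 1 of 100 splits, the real one, gave as many, the smallest share these splits can reach. By this share chance is unlikely but not excluded, since the highest other count was 4329. That split put WT neutrophil 1 with KO neutrophils 1 to 4 and KO neutrophil 5 with WT neutrophils 2 to 4, so a structure among these arrays close to the genotype gave nearly as many genes. Chance cannot be excluded for the 6 lists in neutrophils (67 of 100 splits gave as many, highest other 16), the 1 gene (15 of 84, highest other 2) and the 1 list (66 of 84, highest other 9) in macrophages, or the 7 lists in microglia (17 of 100, highest other 9). For the 0 genes in microglia the splits say nothing, since every split reaches that count (100 of 100, highest other 1). Between cell types, only the real split reached 12007 genes in WT neutrophils against microglia (1 of 100, highest other 7050) and 8285 in WT macrophages against microglia (1 of 84, highest other 349). The same held for 11402 in WT neutrophils against macrophages (1 of 35, highest other 9446). Chance is unlikely for these counts, least clearly where another split came close. For differences in the change with genotype the splits redrew the genotype in both cell types at once. They stand for no change in either cell type, so they cannot show whether the change differs between cell types. Only the real split reached 1518, but another came close (1 of 100, highest other 1376). For 1280, 3 of 100 splits gave as many, a share under 0.05. However, 2 of these were other splits and the highest, 1927, exceeded the real count, so chance is not excluded. Between macrophages and microglia every split reaches a count of 0 (100 of 100, highest other 1), so the splits say nothing there.

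Of the 1526 transcript clusters that were 2-fold or more higher in KO neutrophils, 1396 were brighter by at least 1 log2 unit in WT macrophages than in WT neutrophils, and 1345 in WT microglia. Both differences are taken from the same WT neutrophil arrays, so a cluster that these arrays read low tends to enter both sets. The overlap is therefore partly built in and is not evidence of a cause. Macrophages like the sorted ones in the KO neutrophil samples are argued against: genes abundant in WT macrophages and lower by 5 log2 units or more in WT neutrophils implied a median share of 1.79% (upper quartile 4.11%), where the pattern needed 53.6% (lower quartile 38.1%), with H2-Ab1 at 0.113%, H2-DMa at 4.83% and Pld4 the highest at 8.3%. Microglia are argued against in the same way, at 2.87% (upper quartile 8.67%) against 42.7% (lower quartile 26.8%), with Siglech the lowest named gene at 0.446% and Pld4 the highest at 15.4%. The shares rested on 10 clusters abundant in macrophages and 17 abundant in microglia, and on the 1396 and 1345 clusters of the pattern. A 2-fold rise in KO was required of the pattern but not of the abundant clusters. This raises the share the pattern needed, so the distance between the 2 shares is partly set by the choice of clusters. By the abundant clusters neither cell type explains the pattern as a whole, and a smaller share of either stays open. Patchy detection of broadly expressed genes in the WT neutrophil arrays cannot be told apart from a change with genotype: of 259 broadly expressed clusters that were low in a WT neutrophil array 64.1% were low in 1 array only, but 124 of these 166 were low in WT neutrophil 4, and among the other 3 arrays the share was 56.3% of 135. The median level of all 2015 broadly expressed clusters as a covariate left 5.05% of the 1526 called, with a smaller change and a larger SE (median change 1.41 before and 0.57 with it, SE 0.33 and 0.44), and that of the 1154 that had not passed left 65.1% (median change 1.14, SE 0.32), but 429 of the 1526 are among the 2015 and the 1154 were chosen by the calls, so neither decides, and an effect of TREM1 loss stays open as untested.

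Cartilage genes such as Prg4, Dcn and Mia varied between arrays of a group and differed between genotypes. The values do not show loss of TREM1 acting alike in every cell type. The mean of the cartilage list differed by -1.24 (SE 0.39) in neutrophils and 1.07 (SE 0.41) in macrophages, a difference of -2.31 (SE 0.56). Without WT neutrophil 4 the neutrophil value was -0.67 (SE 0.31) and the difference -1.74 (SE 0.43). The list was written after differences of such genes had been seen, so its mean and counts of its members describe them and are not an independent test. RNA of cartilage tissue in WT neutrophil 4 is a candidate source there that was not tested independently. In that array 14 of 25 cartilage genes lay more than 1 log2 unit above the other 3 WT neutrophil arrays. Among them were Prg4 at 17.43 and the proteoglycan gene Acan at 12.56 (others 7.71 to 7.89). The cartilage collagen gene Col2a1 was not raised, at 6.18 (others 5.45 to 6.33), and the CD45 and CD11b gates would remove cartilage cells. A preparation shared by microglia arrays of the same number may add to the spread, with a correlation of 0.94 between WT and KO arrays (6 pairs, exact permutation p = 0.0181), but it did not pass over 39 lists (adjusted p = 0.343), and neutrophil markers had -0.85 (exact permutation p = 0.00556). An effect of genotype that differs between cell types stays open as untested.

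KO microglia 2 and 4 held granule genes of neutrophils, with Ngp at 13.11 and 10.42 (WT microglia 5.53 to 7.60), S100a8 at 12.04 and 9.15 (4.65 to 7.11) and Camp at 12.46 and 8.04 (4.63 to 5.29), while Lcn2 was above the WT microglia range (6.51 to 9.93) in KO microglia 2 (12.45) and not in KO microglia 4 (9.23). Neutrophils like the sorted ones are argued against, since S100a8 minus Ngp was -1.08 and -1.26 in these arrays and 2.25 to 10.34 in the neutrophil arrays. Early granulocyte precursors that make azurophil granule proteins cannot be told apart from other sources, since 1 of 4 such genes, Elane at 7.40, exceeded every WT microglia array by more than 1 log2 unit, by 1.08, which is too little to decide. The labels give the microglia gate as Ly6G positive, and a Ly6G negative gate would remove Ly6G positive neutrophils while a positive one would not. Neutrophil markers averaged 6.57 in WT microglia and 14.4 in WT neutrophils, so the label may be an error, which was not tested. An effect of genotype present in 2 of 6 arrays stays open as untested.

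Arrays far from the others of their group were found in 10 of 108 groups of values, where chance gives about 1 in 20, or 5. Many of these groups share arrays and were chosen by the results, so 5 is only a rough reference for 10. The mean correlation with its group was 0.933 in WT neutrophil 4 (others 0.959 to 0.962) and 0.974 in KO neutrophil 5 (others 0.983 to 0.985). The mean of the disease-associated microglia list was 13.5 in WT neutrophil 1 (others 12.5 to 12.6). In KO neutrophils Lipo3 was at 11 in array 5 (others 11.9 to 12.2) and Tmem229b at 7.04 in array 2 (others 8.32 to 8.5). Trem1 was at 7.62 in WT microglia 1 (others 9.55 to 10.4). In KO microglia Ifitm3 was at 13.7 in array 5 (others 12.9 to 13.1) and the mean of the immediate early list at 11.9 in array 3 (others 11 to 11.3). KO microglia 2 had a mean of 8.81 for neutrophil markers (others 6.45 to 7.26) and 6.55 for endothelial markers (others 6.33 to 6.41).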

How the results depend on the processing

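Settings with a covariate and those that leave out 2 arrays, or WT neutrophil 4 in a fit of neutrophils alone, were chosen after seeing the data. The cause of a change was not tested unless stated. Over all settings, named genes that passed gave 3120 values with the same direction and side of the threshold, 289 that no longer passed and 7 with the other sign. The loss was uneven: with the level of broadly expressed genes as a covariate 13 named neutrophil results stayed the same, 60 no longer passed and 8 changed sign, of which Cd86 had not passed before. With the level of those that had not passed 66 stayed the same, 15 no longer passed and 0 changed sign. In both settings, results that stayed the same included some that passed neither before nor with the covariate: Il27, Cxcl9, Traf1, Zc3h12a and Pde4b. Fewer than 13 and fewer than 66 calls were therefore kept. Of 218 named results 162 passed in the main fit. Among the settings chosen beforehand, 58 of these no longer passed with the replicate number as a fixed block, which was fitted on only the arrays compared. With only the arrays compared in the fit and no block 46 no longer passed. With the number as a random block in the fit on all arrays 1 no longer passed. With 3 to 6 arrays per group, changes near 0.5 log2 were seldom recovered in simulated data.

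With only the arrays compared in the fit, which leaves fewer degrees of freedom and takes the spread from those arrays alone, the counts of genes were 1084 in neutrophils, 9 in macrophages (2 lists), 7299 for WT neutrophils against macrophages, and 821 and 631 for the differences of the neutrophil change from microglia and macrophages. The Trem1 call in neutrophils ended after quantile normalization over all arrays (-1.04, adjusted p = 0.0759) and median centring (-1.11, 0.071). The macrophage lists were 0 after quantile normalization over all arrays or within cell types, and 3 with array weights, which gave 3 lists in microglia. With an estimated correlation 0 lists passed in neutrophils, macrophages and microglia, and with fry 16, 0 and 0. As a fixed replicate block, the number was fitted on only the arrays compared, so its counts stand beside those of that fit, such as 1084 in neutrophils. It gave 1207 genes in neutrophils, where the Trem1 call ended (-1.21, adjusted p = 0.0618), and 0 genes and 3 lists in macrophages. Between WT cell types it gave 7571, 4563 and 5353 genes (neutrophils against microglia, macrophages against microglia, neutrophils against macrophages), and 177 and 0 for the differences from microglia and macrophages. As a random block in the fit on all arrays, the number gave 4398 genes in neutrophils, where Trem1 passed (-1.22, adjusted p = 0.0368). The numbers did not pair the samples by the correlation of their residuals.

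With the cartilage mean as a covariate 1477 genes passed in neutrophils, and 389 and 6 for the differences from microglia and macrophages. Without KO microglia 2 and 4, 1 gene and 1 list passed in microglia, and neutrophil markers changed sign (adjusted p = 0.997). Without WT neutrophil 4 and with neutrophils alone, 977 genes passed. With the level of broadly expressed genes as a covariate, which differed between the genotypes, 212 genes and 3 lists passed in neutrophils, and 45 and 9 genes for the differences. The Trem1 call ended (-1.96, adjusted p = 0.132), and the sign changed for Cln8 (-0.54), Mia (0.69), Dcn (0.64), Wif1 (1.31), Lum (1.00), Daam2 (0.17), Cd86 (-0.25), P2ry12 (0.02) and the oxidative phosphorylation list (adjusted p = 0.806). With the level of those that had not passed, 1980 genes passed, and 777 and 430 for the differences.

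Leaving out 1 array at a time, the genes that passed were 2883 to 5557 in neutrophils, 0 to 9 in macrophages, 0 to 1 in microglia, and 724 to 2611 and 786 to 2790 for the differences. Trem1 in neutrophils ranged from -1.35 to -1.01. Lists ranged from 0 to 6 in macrophages and 3 to 10 in microglia.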

Other observations

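Beyond the markers of the gates, the WT cell types differed in the levels of cell cycle and oxidative phosphorylation genes. Of 24 cell cycle genes 24 were lower in neutrophils than in microglia (median -3.61, adjusted p = 6.84e-12, and adjusted p = 0.0714 with an estimated correlation) and 23 lower in macrophages than in microglia with 1 higher (median -3.58, adjusted p = 1e-14, and adjusted p = 0.0191 with an estimated correlation). Their mean level was 11.06 ± 0.64 (SD, n = 6) in microglia, 7.60 ± 0.25 (n = 4) in neutrophils and 7.79 ± 0.26 (n = 3) in macrophages. Of 27 oxidative phosphorylation genes 23 were lower in neutrophils than in microglia (median -0.88, adjusted p = 0.000178, and adjusted p = 0.415 with an estimated correlation) and 22 lower than in macrophages (median -1.31, adjusted p = 2.94e-09, and adjusted p = 0.368 with an estimated correlation). The 2015 broadly expressed clusters were also lower in the WT neutrophil arrays, with medians from -1.03 to -0.56 relative to the macrophage and microglia arrays. The differences of this list were therefore not shown to be particular to it.

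Inflammatory and antigen presentation genes also differed between the WT cell types. Of 23 NF-kB targets 16 were higher and 5 lower in neutrophils than in microglia (median 1.81, adjusted p = 0.000115, and adjusted p = 0.202 with an estimated correlation). Of 13 MHC class II genes 9 were higher in macrophages than in microglia (median 1.74, adjusted p = 7.8e-11, and adjusted p = 0.00943 with an estimated correlation) and 12 were lower in neutrophils than in macrophages (median -4.61, adjusted p = 8.24e-12, and adjusted p = 0.0158 with an estimated correlation). Of 26 interferon response genes 15 were higher and 1 lower in macrophages than in microglia (median 1.29, adjusted p = 1.38e-08, and adjusted p = 0.0378 with an estimated correlation).

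Across genes, the change with genotype in neutrophils correlated at 0.10 with that in microglia and -0.10 with that in macrophages, and the changes in macrophages and microglia correlated at 0.06. The Trem1 value was 15.98 in KO neutrophils, above the 13.96 of WT macrophages. Since the deleted part of the gene is not stated, this value does not show that intact Trem1 RNA remained.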
